A study of Xenopus laevis with 22 samples.

How the data were processed

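The estimated counts (expected counts) had been made before deposition by eXpress, which shares fragments with several possible origins among targets, as the column names per the file headers show. No normalization had been applied to the deposited estimated counts. The uniquely assigned counts had been deposited in the same tables and count fragments aligned to a single target, per the file headers. Per the submitters' processing notes STAR, Bowtie2, Bowtie, eXpress, DESeq and HOMER were used, with no version or role given. Peaks had been called by the authors with HOMER on the pooled replicates against pooled input, with an FDR of 0.001 and at least 4-fold over input and over the local region, per the file headers. The score column of both deposited peak sets holds a single value throughout, so the deposited scores carry no ranking. The inputs have no files. Peak positions and target positions are on the JGIv7b scaffolds, and no genome sequence was used. Per the labels' protocols 20 animal caps went into each RNA library and about 300 into each ChIP condition. Induction was with 20 µM dexamethasone at 22 °C, and no dexamethasone is given for E2f4-GFP without Multicilin or its input. The RNA library kit keeps no strand information.

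Of the 18 RNA libraries, 16 listed 24383 targets and 2 listed 35532, of which 11149 had other positions. The latter were replicate 1 of the dnE2f4 group at 3 h and replicate 3 of the dnE2f4 group at 9 h. The same symbol stood beside 82.4% of the common targets in both sets. By target, the spread of log2 ratios in the affected groups was 0.60 to 0.68 across the target sets and 0.33 and 0.49 within a set, and within the other groups it ran from 0.29 to 0.65, highest in pairs holding the library labelled Multicilin 9 h replicate 2. Summed by symbol it was 0.39 to 0.52 across sets and 0.31 and 0.46 within, so at 3 h most of the gap closed. The 9 h values within a set, 0.49 and 0.46, come from a pair holding the library labelled dnE2f4 replicate 2, whose e2f4 was opposite to its label. So do the highest values across sets, 0.68 and 0.52. At 9 h there was therefore no sound reference within a set. The fit planned before the data were examined held all 18 libraries. It was replaced by the 16 on the common targets, because the targets differ, and the join of 18 by name and the sums by symbol are among the alternatives. No pair of libraries in a group was a duplicate, the lowest chi-square per degree of freedom being 14.7.

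Estimated counts were rounded and filtered with filterByExpr. They were normalized by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, with a mean per group and no other term. Targets passed at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 was the alternative tool. Most tests and alternatives, the lists and the panel of named genes were set before the data were examined. Not set beforehand were the tests of peaks near list members and by peak class. The overlaps of dnE2f4 calls between times, and of changes from 3 to 9 h with dnE2f4 at 6 h, were also added. The 14-library fit, without both libraries labelled replicate 2 at 9 h, was added after e2f4 was found opposite to their labels and was chosen for the calls on dnE2f4 after the 16-library fit had called none. Changes with time were called from the 16 libraries, and gene lists were taken from the 14. Overlaps of dnE2f4 calls with the time course used time calls from the 14 libraries (5153 rises from 3 to 6 h). The 14-library fit tested 20043 targets and the 16-library fit 19567.

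Pairing was checked once, since the labels number the replicates without saying what a number stands for. Deviations from the group mean, in libraries with the same number, correlated at 0.26 and 0.45 at 3 h, 0.80, 0.60 and 0.71 at 6 h, and 0.15 and -0.35 at 9 h. With different numbers they ran from -0.61 to 0.11 at 6 h, so the libraries of 6 h were paired by number. At 3 and 9 h the deviations of the dnE2f4 libraries left on the common targets mirror each other. Both 9 h values therefore depend on the pair opposite to its labels. Since the labels do not say what a number stands for, the calls given leave the pairing out. Replicate number entered as a block in an alternative, with an effect per number shared by all groups in the fit. In fits holding several times this takes a number to mean the same at each of them. That was not checked, since deviations were compared within a time only.

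As a self-test, 200 targets in simulated counts with the spread of these libraries were changed at each time, in classes of 67, 67 and 66 targets at 4-fold, 2-fold and 1.5-fold. The 14-library fit recovered 85, 31 and 0% of them at 3 h, 90, 37 and 2% at 6 h and 64, 9 and 0% at 9 h, with 0 to 5 unchanged targets called. The 16-library fit recovered 75, 25 and 5%, 94, 25 and 2%, and 78, 13 and 2%. Planted targets were drawn at random among those over 2 CPM, from a common mean for all libraries, with no libraries exchanged. In the real 16 libraries the pair labelled replicate 2 at 9 h widened the spread of targets that dnE2f4 changes. There 0 targets passed at 6 h. These recoveries therefore do not give the power of the 16-library fit for such targets. The 4-fold class was added after a version holding only the smaller changes had recovered few.

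In all, 18 gene lists of 642 symbols were fixed, and 561 symbols matched by current or older symbol without regard to case, copies included. Tables held 13475 distinct symbols and 519 targets without a symbol. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1) on log2 CPM with a prior count of 2. List medians come from those log2 CPM values and can differ slightly from medians of edgeR fold changes. Counts of members were taken over all targets and adjusted over the list alone.

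Named genes were a panel of 29 symbols, of which 1 was not measured, each standing by its most abundant target. To these were added the 5 largest rises and falls per comparison with a mean of at least 2 CPM and no overlap between groups, the 3 largest per direction for a change between times, and up to 4 members per list, or the 2 most abundant where none passed. A planned choice of peaks by deposited score was not possible. Of 102 named targets 13 overlap a target with another symbol, among them plk4, stil, sfi1, cetn2, bbs12 and cdc20b.

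Peaks were compared with bedtools 2.31.1, by at least 1 base, at a reciprocal overlap of 0.5, and after a move of 10 kb. A target had a peak when a peak lay within 1 kb of its start, taken from the deposited position and strand, or within 5 kb in an alternative. Matched level used 10 classes of mean CPM, and intervals were 95% binomial. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.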

Results

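RNA-seq of Xenopus laevis animal caps covered 6 groups of 3 libraries, made 3, 6 and 9 h after hormone switched on a Multicilin fusion, with or without co-injected dominant-negative E2f4 (dnE2f4). The 18 libraries held 9159519 to 38099850 estimated fragments each. Between 67.9 and 69.6% of the alignable fragments fell on a single target in 16 libraries, and 58.3 and 64.4% did so in the 2 libraries scored against a different target set. ChIP-seq of E2f4-GFP at 6 h gave a single peak set without Multicilin and a single set with it, each pooled by the authors from 2 replicates. Nothing in the labels states that replicates came from separate animals or clutches, although they are called biological replicates, so the p-values measure spread between these samples. Because Xenopus laevis carries near-identical gene copies that share fragments, and the library kit was not stranded, the level of any single copy or of overlapping genes is uncertain.

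The e2f4 transcript, raised by the injected dnE2f4 RNA, is given before anything else for every library, since it checks the labels. Summed over the targets with that symbol it stood at 29.1 ± 3.23 CPM (counts scaled by library size, mean ± SD, n = 3) in the libraries labelled Multicilin 3 h and 7060 ± 2120 in those labelled dnE2f4 3 h (n = 3). At 6 h the values were 30.1 ± 8.21 and 4840 ± 1470 (n = 3 and 3). At 9 h the library labelled Multicilin replicate 2 carried 1520 CPM and the library labelled dnE2f4 replicate 2 carried 15.7 CPM, opposite to their labels. The other libraries labelled Multicilin 9 h had 16.2 and 17.0 CPM, and the others labelled dnE2f4 9 h had 1420 and 1570 CPM. The centriole kinase plk4 was also reversed in that pair, at 166 CPM in the library labelled Multicilin replicate 2 and 766 CPM in the library labelled dnE2f4 replicate 2.

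**Figure D1:**
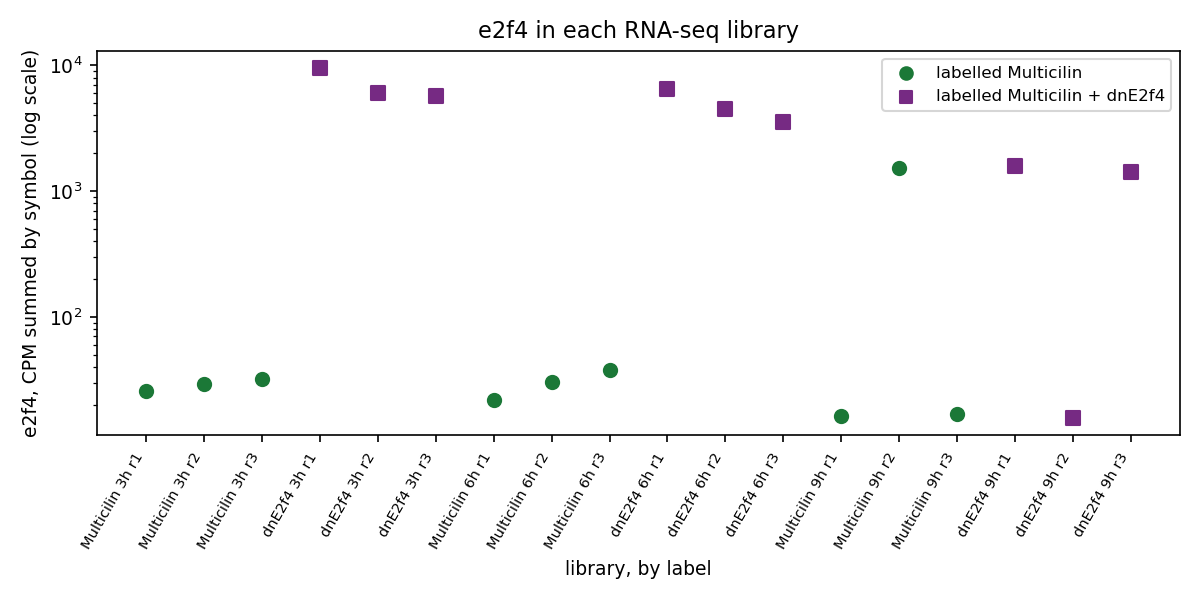
Summed e2f4 level in CPM (log axis) in each of the 18 libraries, placed by label; circles are libraries labelled Multicilin and squares libraries labelled dnE2f4. At 9 h the libraries labelled replicate 2 lie on the opposite side to their labels, at 1520 and 15.7 CPM.

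With labels as deposited, no target passed for dnE2f4 at any time in the 16 libraries sharing a target set. There edgeR gave 0, 0 and 0 targets at 3, 6 and 9 h (871, 1904 and 120 at unadjusted p under 0.05), and DESeq2 gave 37, 137 and 1. The dnE2f4 calls below therefore come from 14 libraries, without the pair labelled replicate 2 at 9 h. That choice was made after e2f4 had contradicted the labels and after the counts of 0 had been seen, and it is not the fit planned. A separate fit, set before the data were examined, used the 6 libraries of the 6 h groups alone and so neither library of that pair. It called 403 targets at 6 h (47 higher, 356 lower), and 369 of them were among the 690 called from 14 libraries. Fits with the compared groups alone gave 2 targets at 3 h, against 57 from 14 libraries, and 1 at 9 h without the pair, against 227.

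As Multicilin caps aged from 3 to 9 h, cilium and centriole genes rose and cell-cycle genes fell. The pluripotency gene pou5f1 dropped from 405 ± 74.5 to 1.16 ± 0.696 CPM (mean ± SD, n = 3 and 3, log2 fold change -8.42 ± 0.59, mean ± SE) and the membrane protein gene lrrn1 from 158 ± 25.4 to 0.632 ± 0.181 CPM (-7.93 ± 0.45). The cytokine receptor gene il20ra rose from 0.0119 to 25.7 CPM (n = 3 and 3, edgeR adjusted p = 1.6e-08). It had almost no counts at 3 h, so its log2 fold change of 10.31 ± 0.59 is not an exact size. Transcripts of fam188b2 and c7orf31, neither counted in any Multicilin library at 3 h, reached 10.4 and 9.98 CPM at 9 h (n = 3), so no fold is given. Of 19567 targets tested in 16 libraries, edgeR called 12909 between 3 and 9 h (6693 higher, 6216 lower) and 9486 between 3 and 6 h (4889 higher, 4597 lower). In the caps with dnE2f4 the counts were 11881 (6180 higher, 5701 lower) and 8212 (4434 higher, 3778 lower). Scaling to library size alone moved the splits to 4962 higher and 7865 lower for 9 h and 3591 and 6348 for 6 h in Multicilin caps, and to 4662 and 7168 and 3441 and 4952 in dnE2f4 caps, so the balance of rises and falls depended on the scaling. No RNA library lacked Multicilin, so these changes include those of unmanipulated development, and both 9 h groups contain a library, labelled replicate 2, whose e2f4 level contradicts its label.

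The gene lists were followed over time in the 14 libraries. Axoneme genes rose nearly throughout: 116 of 118 targets were higher at 9 h than at 3 h in Multicilin caps and 1 lower (1 lower and 116 higher adjusted over the list alone, median log2 fold change 3.22), and 116 were already higher at 6 h (median 2.32). Centriole assembly genes had 72 higher and 6 lower of 88 at 9 h (72 and 7 adjusted over the list alone, median 1.99), and 73 higher and 6 lower at 6 h. For intraflagellar transport and BBSome genes 64 rose and 1 fell of 69 at 9 h (64 and 1 adjusted over the list alone), against 61 and 1 at 6 h. G1/S genes fell in 94 and rose in 9 of 118 (96 and 9 adjusted over the list alone, median -2.07). G2/M genes fell in 81 and rose in 24 of 139 (81 and 25 adjusted over the list alone), and multiciliated-cell regulators fell in 24 and rose in 7 of 41, unchanged when adjusted over the list alone. Camera called all 6 of these lists at 9 h and lost every call with an estimated correlation. That gave axoneme, centriole and transport genes adjusted p = 0.146 with an estimated correlation, G1/S genes adjusted p = 0.119 with an estimated correlation, and G2/M genes and regulators adjusted p = 0.208 with an estimated correlation. The camera calls for Notch genes (adjusted p = 0.208 with an estimated correlation) and neural genes (adjusted p = 0.46 with an estimated correlation) were lost too. Among the other lists, with lower then higher targets at 9 h, counts were 5 and 20 of 37 for ionocyte genes, 13 and 19 of 47 for goblet, 3 and 3 of 13 for small secretory cell, 2 and 2 of 8 for basal, 21 and 2 of 42 for neural, and 4 and 4 of 16 for neural crest genes. They were 0 and 3 of 18 for mesoderm, 7 and 5 of 23 for endoderm, 15 and 4 of 31 for Notch, 21 and 18 of 58 for stress, 4 and 1 of 11 for dexamethasone and 9 and 5 of 29 for housekeeping genes. Adjusted over the list alone these stayed the same except 4 and 3 for neural crest, 0 and 0 for mesoderm and 8 and 4 for housekeeping genes.

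At 3 h, dnE2f4 already lowered genes of centriole assembly. The kinase plk4, which starts centriole assembly, fell from 22.7 ± 5.03 to 5.73 ± 1.88 CPM (mean ± SD, n = 3 and 2, log2 fold change -2.0 ± 0.33, edgeR adjusted p = 0.0331). Its centrosomal partner cep152 fell from 216 ± 3.1 to 96.8 ± 13.4 CPM (-1.15 ± 0.16, edgeR adjusted p = 0.0159), and ccdc67, the older symbol of deup1 from the deuterosome, where centrioles form in bulk, from 103 ± 18.6 to 31.7 ± 3.12 CPM (-1.70 ± 0.28, edgeR adjusted p = 0.0331). The homeobox gene otp had the largest fall, from 29.7 to 3.42 CPM (-3.13 ± 0.46), and the Notch ligand dll1 rose from 20.5 to 40.8 CPM (1.00 ± 0.17). The transcription factor foxj1 (log2 fold change -0.50, edgeR adjusted p = 0.618) and the dynein gene dnai1 (-0.46, edgeR adjusted p = 0.665) did not pass, although 1 of the 2 other foxj1 targets did. With replicate number as a block foxj1 passed as well (edgeR adjusted p = 0.0193), as did both its other targets, and dnai1 did not.

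In full, edgeR called 57 of 20043 targets at 3 h, 54 lower and 3 higher (62 and 3 with library size alone), DESeq2 called 403, and 46 of the 57 changed at least 2-fold. With replicate numbers as a block the count was 621. It was 2 with the compared groups alone, 2 without dnE2f4 replicate 2 or replicate 3, and 3 without Multicilin replicate 2, so nearly all 3 h calls depended on single libraries. The most abundant e2f4 target, on scaffold 15416 (1879975 to 1902638, minus strand), rose by 8.28 ± 0.30. A second e2f4 target rose by 1.67 ± 0.29 from estimated counts and fell by -0.44 from uniquely assigned ones, so its level is uncertain. The falls included tp73 (-1.65 ± 0.22), cetn2 (-1.47 ± 0.14), cenpj (-0.81 ± 0.14), the centriole gene rttn (-1.24 ± 0.16), both foxn4 targets (-1.56 and -1.57), ccna1 (-2.29), dmrta2 (-2.38), sstr5 (-2.36) and dnase1l2 (-2.51). Of the other panel genes stil (-1.21), sass6 (-0.62), ccno (-0.69), cdc20b (-1.12), ccp110 (-0.67) and myb (-0.80) did not pass, and all of them passed with the block.

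By 6 h most centriole assembly genes were lowered by dnE2f4, and the dynein genes dnai1 and dnah9 did not pass. Levels of plk4 fell from 337 ± 68.4 to 62.5 ± 18.6 CPM (mean ± SD, n = 3 and 3, log2 fold change -2.43 ± 0.27, edgeR adjusted p = 0.000847), of cep152 from 371 ± 51.3 to 106 ± 12.5 CPM (-1.81 ± 0.14, edgeR adjusted p = 0.000152), and of ccdc67 from 388 ± 121 to 97.2 ± 16.8 CPM (-2.0 ± 0.24, edgeR adjusted p = 0.0016). The centriole scaffold gene stil fell from 454 to 134 CPM (-1.76 ± 0.22), and the multiciliated-cell cyclin ccno from 944 ± 183 to 465 ± 59.2 CPM (-1.02 ± 0.21). The centriole gene rttn fell 8.36-fold, from 97.6 ± 9.05 to 11.7 ± 0.515 CPM (-3.07 ± 0.14, edgeR adjusted p = 4.18e-07). Neither foxj1, at 751 ± 108 and 588 ± 72.1 CPM (-0.35 ± 0.19, edgeR adjusted p = 0.4), nor the axonemal dynein gene dnai1, at 555 and 430 CPM (-0.37, edgeR adjusted p = 0.339), passed, although 1 of the 2 other foxj1 targets did. With the block foxj1 passed (-0.35, edgeR adjusted p = 0.0296), as did both its other targets, and dnai1 did not.

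**Figure D2:**
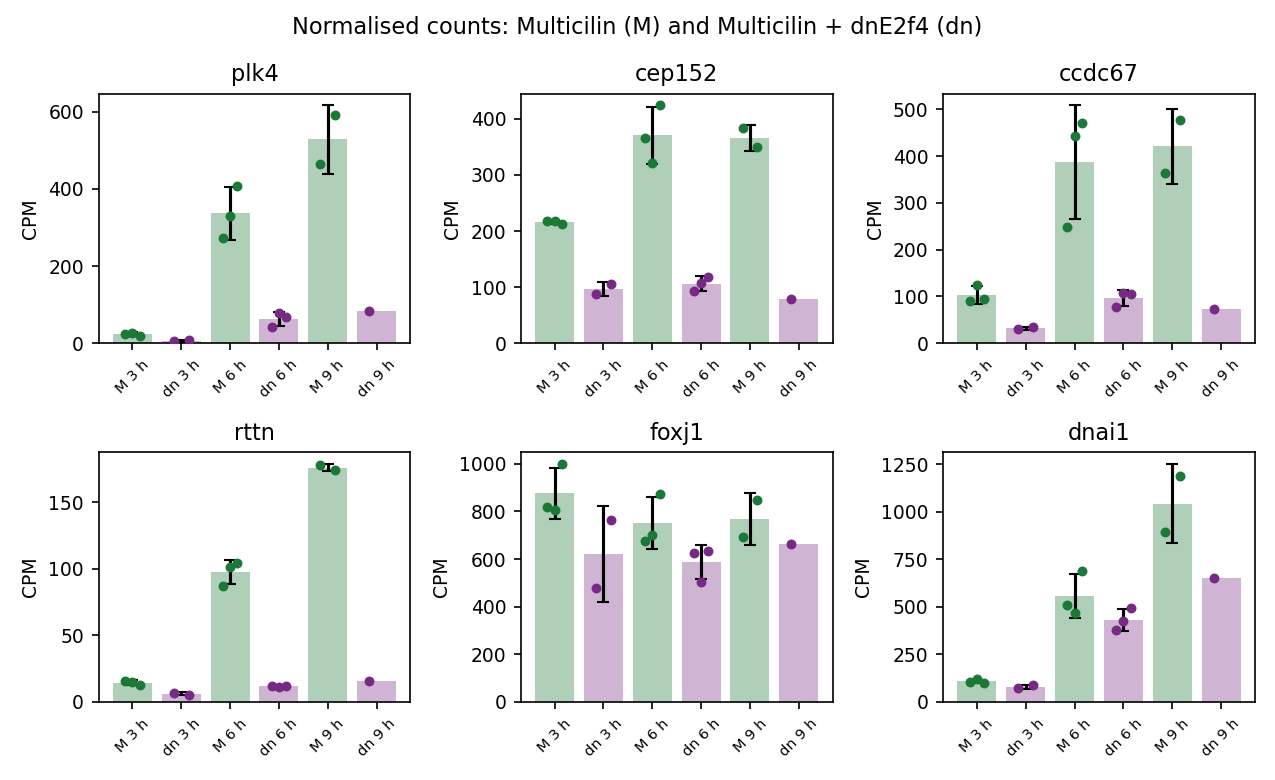
Level in CPM of plk4, cep152, ccdc67, rttn, foxj1 and dnai1 at 3, 6 and 9 h in Multicilin caps and caps with dnE2f4; bars are means, error bars SD and points single libraries of the 14. At 6 h plk4 stood at 337 without and 62.5 with dnE2f4, while foxj1 stood at 751 and 588.

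At 6 h edgeR called 690 of 20043 targets, 174 higher and 516 lower (297 and 384 with library size alone), of which 340 changed at least 2-fold, and DESeq2 called 1409. Blocking on replicate number gave 3191 (1405 higher, 1786 lower). The count fell to 431 and 205 without Multicilin replicate 2 and 3, and to 241 and 285 without dnE2f4 replicate 2 and 3. The largest falls were in the potassium channel gene kcna4 (-3.83 ± 0.54 and -3.33 ± 0.41 for its 2 targets), the membrane protein gene tmem221 (-3.47 ± 0.42), the germ-cell cyclin ccna1 (-3.41 ± 0.37 and -2.68 ± 0.49) and rttn. Rises were led by the Notch effector hes5, from 1.15 to 9.16 CPM (2.91 ± 0.73, edgeR adjusted p = 0.049), the homeobox gene dlx2 (1.98 ± 0.35), the receptor gene rtn4r (1.98 ± 0.39) and the growth factor gene pdgfa (1.96 ± 0.44). Other panel genes past the threshold were sass6 (-0.79 ± 0.18), cenpj (-0.89 ± 0.12), cdc20b (-1.38 ± 0.29), ccp110 (-1.19 ± 0.13), myb (-0.94 ± 0.13) and tp73 (-1.28 ± 0.18), and e2f4 itself rose by 8.48 ± 0.30. Panel genes rfx2 (-0.16), rfx3 (-0.54), dnah9 (-0.32), tekt2 (-0.31), ift88 (-0.48), ccna2 (0.32), pcna (0.73), cdk1 (-0.85), e2f1 (-0.28), e2f5 (0.15), cep57 (0.17), itln1 (0.86) and the most abundant foxi1 target (0.45) did not pass. Of these rfx3, ift88, ccna2, pcna, cdk1 and itln1 passed with the block. At its most abundant target the Multicilin symbol mcidas was lower at 3, 6 and 9 h (-0.70 ± 0.26, -0.89 ± 0.23 and -1.2 ± 0.36). It did not pass at 3 or 6 h (edgeR adjusted p = 0.483 and 0.0585). With the block, which takes replicate numbers to mean the same at every time, it passed at both (edgeR adjusted p = 0.00649 and 0.000161). Summed by symbol in all libraries but the 9 h pair, mean mcidas with dnE2f4 was 0.76, 0.616 and 0.61 of that without it at 3, 6 and 9 h.

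Centriole assembly genes made up the largest response of any list at 6 h: 52 of 88 targets were lower and 0 higher (70 lower and 1 higher adjusted over the list alone), the median log2 fold change was -0.86, and camera kept the call (adjusted p = 0.0198 with an estimated correlation). With the block added, the comparison with other genes in camera no longer passed (adjusted p = 0.265 with an estimated correlation). The fry test passed (limma fry adjusted p = 0.000432). It asks whether the list shifted in a common direction, and not whether it shifted more than other genes. Among the lower centriole targets were cetn2 (-1.37 ± 0.12) and sfi1 (-1.55 ± 0.14), whose product binds centrins. Multiciliated-cell regulators had 8 lower and 2 higher of 41 (13 and 2 adjusted over the list alone, adjusted p = 0.0896 with an estimated correlation in camera). The 2 higher ones were targets of e2f4, the symbol of the injected RNA. Whether the second of them rose itself or through shared fragments was not tested. The regulator of multiciliated cells foxn4 was lower at both its targets (-1.90 ± 0.18 and -1.76 ± 0.19). Axoneme genes had 5 lower and 0 higher of 118 (6 and 0 adjusted over the list alone, 48 lower with the block, adjusted p = 0.377 with an estimated correlation in camera). Those past the threshold included the assembly factors dnaaf2 (-0.73) and dnaaf1 (-0.57), the kinase gene stk36 (-0.67) and the tektin gene tekt3 (-0.96). By library, the median log2 CPM of axoneme symbols relative to the 6 h mean was 0.02 to 0.29 in Multicilin caps. With dnE2f4 it was -0.18 to -0.13, so the list as a whole lay slightly lower. Intraflagellar transport and BBSome genes had 7 lower and 0 higher of 69 (35 and 0 adjusted over the list alone; 47 lower with the block, adjusted p = 0.143 with an estimated correlation in camera). Among them were bbs12 (-1.53), kif3a (-1.38), ift74 (-0.91) and tctn3 (-0.63).

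Cell-cycle genes split in both directions at 6 h. G1/S genes had 6 lower and 1 higher of 118 (8 and 4 adjusted over the list alone; 20 and 13 with the block), with tyms (-1.2) and pold3 (-0.94) lower. Camera did not call the list (adjusted p = 0.0548, or adjusted p = 0.551 with an estimated correlation). G2/M genes had 4 lower and 6 higher of 139 (7 and 19 adjusted over the list alone, or 18 and 36 with the block). Both bora targets were lower (-1.21 and -0.93) and both kpna2 targets were higher (1.02 and 0.93). Notch genes had 4 higher and 0 lower of 31 (5 and 0 adjusted over the list alone, camera adjusted p = 0.377 with an estimated correlation). In this list 3 dll1 targets rose (1.5, 1.64 and 0.65), as did hes1 (1.11). Ionocyte genes had 1 higher and 0 lower of 37 (4 and 0 adjusted over the list alone, camera adjusted p = 0.551 with an estimated correlation), the second foxi1 target (1.30 ± 0.18).

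Neural genes had 3 lower and 3 higher of 42 (6 and 6 adjusted over the list alone), with sox3 (-1.39) and ncam1 (-0.87) lower and 3 hes5 targets higher (2.91, 2.83 and 2.66). Their median was -0.12 and their mean 0.10, of opposite sign. Stress genes had 2 higher and 0 lower of 58 (2 and 0 adjusted over the list alone; 14 higher and 4 lower with the block), among them gadd45g (1.2). The dexamethasone list had 1 higher and 0 lower of 11, dusp1 (0.93), and the same count adjusted over the list alone. The goblet list had 1 higher and 0 lower of 47, grhl2 (0.80), and 0 and 0 adjusted over the list alone. No member passed, either way of adjusting, among small secretory cell genes (13 targets, pcsk1 -0.18, chga 0.43), or basal genes (8 targets, itga6 0.44 and 0.65). The same held for neural crest genes (16 targets, tfap2a 0.81, msx1 0.76), mesoderm genes (18 targets, acta2 0.20, wnt8a -0.16), endoderm genes (23 targets, endod1 -0.25, a2m 0.22) or housekeeping genes (29 targets, eef1a1 0.02 and 0.06). With the block, lower then higher targets were 0 and 1 for small secretory cell, 0 and 3 for basal, 0 and 4 for neural crest, 1 and 0 for mesoderm, 1 and 1 for endoderm and 3 and 3 for housekeeping genes. They were 8 and 6 for neural, 3 and 7 for goblet, 3 and 9 for ionocyte, 1 and 9 for Notch and 1 and 1 for dexamethasone genes, and 16 and 2 for multiciliated-cell regulators.

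**Figure D3:**
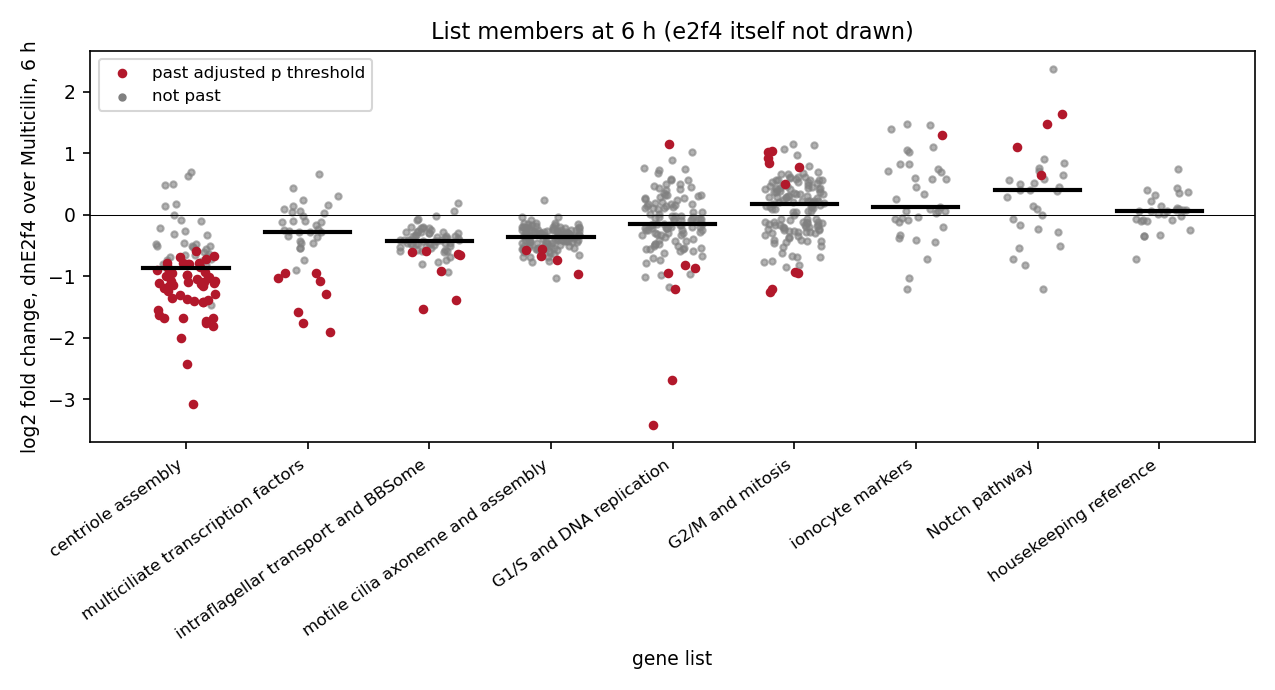
Log2 fold change of each tested member of 9 gene lists with dnE2f4 at 6 h (edgeR); red points are past the threshold, grey points not, and black bars are medians. Centriole assembly genes lie lowest, at a median of -0.86 with 52 of 88 past the threshold.

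At 3 h the lists had smaller counts. Centriole assembly genes had 16 lower and 0 higher (50 and 0 adjusted over the list alone, median -0.66, camera adjusted p = 0.0128 with an estimated correlation, or adjusted p = 0.11 with an estimated correlation and the block). Multiciliated-cell regulators had 5 lower and 2 higher, both e2f4 (11 and 3 adjusted over the list alone). Axoneme genes had 1 lower (61 adjusted over the list alone, 30 with the block, camera adjusted p = 0.084 with an estimated correlation). Transport and BBSome genes had 1 lower (25 adjusted over the list alone; 22 with the block, camera adjusted p = 0.084 with an estimated correlation). G1/S genes had 2 lower (2 adjusted over the list alone; 13 with the block). Notch genes had 1 higher, and the other lists had no member past the threshold over all targets; adjusted over the list alone a neural and a mesoderm target fell and a stress target rose. With the block, lower then higher targets were 16 and 3 for regulators, 6 and 0 for G2/M, 3 and 0 for goblet, 4 and 3 for neural, 1 and 0 for mesoderm, 1 and 2 for Notch, 3 and 3 for stress and 0 and 1 for dexamethasone genes. Camera called the neural crest and Notch lists higher (medians 0.48 and 0.24; limma camera adjusted p = 0.00337 and 0.00342) and lost both with an estimated correlation (adjusted p = 0.39 and adjusted p = 0.175 with an estimated correlation).

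At 9 h centriole genes were again lower with dnE2f4. Levels of plk4 went from 528 ± 87.8 CPM (n = 2) to 83.2 CPM (n = 1, log2 fold change -2.69 ± 0.44, edgeR adjusted p = 0.0157), cep152 from 366 to 78.6 CPM (-2.25 ± 0.23, edgeR adjusted p = 0.00233), ccdc67 from 421 to 74.0 CPM (-2.53 ± 0.40) and stil from 579 to 141 CPM (-2.06 ± 0.35). For rttn the fall was from 176 ± 3.1 to 15.3 CPM (-3.54 ± 0.23, edgeR adjusted p = 2.85e-05). The cyclin gene ccna1 fell from 271 to 16.3 CPM (-4.08 ± 0.57), and the kinase gene cdk7, whose product activates other cell-cycle kinases, fell at a single target from 609 to 46.2 CPM (-3.74 ± 0.43). The neural gene auts2 rose from 0.611 to 6.74 CPM (3.43 ± 0.39).

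A single dnE2f4 library at 9 h remained on the common targets, and it was assumed to vary as the other groups did. With that limit edgeR called 227 of 20043 targets, 43 higher and 184 lower (93 and 131 with library size alone), 212 of them by at least 2-fold. DESeq2 called 1058, and the block gave 2175. The compared groups alone gave 1, and leaving out Multicilin replicate 3 gave 27. The e2f4 target rose by 7.27 ± 0.36. Further falls were in cenpj (-1.40), ccp110 (-1.34), cetn2 (-1.40), sfi1 (-1.91), both foxn4 targets (-2.11 and -2.04), bbs12 (-1.91), tmem221 (-4.32 ± 0.73), a kcna4 target (-3.83) and gpc1 (-3.73), and further rises in pou2f3 (2.07), klf2 (2.04) and bmper (2.00). Among panel genes sass6 (-0.99), ccno (-1.50), cdc20b (-2.10), myb (-0.82), tp73 (-0.93), foxj1 (-0.24), dnai1 (-0.70), ift88 (-0.74) and pcna (1.2) did not pass. All of these but foxj1 and dnai1 passed with the block.

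Centriole assembly genes at 9 h had 37 lower and 0 higher (67 and 1 adjusted over the list alone, median -1.19, camera adjusted p = 0.0201 with an estimated correlation, or adjusted p = 0.258 with an estimated correlation and the block). Transport and BBSome genes had 1 lower (36 adjusted over the list alone; 40 with the block, camera adjusted p = 0.16 with an estimated correlation). Axoneme genes had 0 (0 adjusted over the list alone; 25 lower with the block, camera adjusted p = 0.314 with an estimated correlation). Multiciliated-cell regulators had 2 lower and 1 higher (9 and 2 adjusted over the list alone), G1/S genes 3 lower (4 lower and 2 higher adjusted over the list alone), and G2/M genes 4 lower (10 and 11 adjusted over the list alone). Neural genes had 3 lower (3 adjusted over the list alone), and stress genes 1 higher (1 adjusted over the list alone; 13 with the block). Ionocyte genes had 0 past the threshold over all targets and 6 higher adjusted over the list alone, dexamethasone genes 0 and 2 higher, and housekeeping genes 0 and 1 higher. Either way of adjusting gave 0 for goblet, small secretory cell, basal, neural crest, mesoderm, endoderm and Notch genes. With the block, lower then higher targets were 10 and 3 for regulators, 12 and 6 for G1/S, 18 and 21 for G2/M, 2 and 12 for ionocyte, 1 and 8 for goblet, 0 and 1 for small secretory cell, 0 and 2 for basal, 4 and 1 for neural, 0 and 1 for mesoderm, 0 and 2 for Notch, 0 and 2 for dexamethasone and 0 and 4 for housekeeping genes. Camera called ionocyte and stress genes higher (medians 0.70 and 0.77; limma camera adjusted p = 0.000762 and 1.43e-06) and lost them (adjusted p = 0.314 and adjusted p = 0.188 with an estimated correlation).

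In edgeR, rttn alone passed a test that the dnE2f4 effect itself differed between times. Its fall deepened by -1.83 ± 0.20 from 3 to 6 h (edgeR adjusted p = 0.0194) and by -2.30 ± 0.26 from 3 to 9 h (edgeR adjusted p = 0.0221). Each test called 1 target in edgeR, with 827 and 1509 at unadjusted p under 0.05, and DESeq2 called 23 and 115. The block gave 48 and 157, and the 16 libraries gave 0 and 0. Each call was lost on leaving out most single libraries of the groups compared. Over all targets and without the block, centriole assembly genes had 1 member lower in each test, rttn, and every other list 0. Adjusted over the list alone, from 3 to 9 h G2/M genes had 3 lower and 1 higher, neural genes 2 lower and housekeeping genes 1 higher. With the block, members of several other lists also passed.

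Most genes that dnE2f4 lowered at 6 or 9 h had risen with time in Multicilin caps, with both sets of calls taken from the 14 libraries. The centriole list also rose from 3 to 6 h in caps with dnE2f4, with 66 targets higher and 5 lower of 88 (median log2 fold change 1.23). In Multicilin caps 73 were higher and 6 lower (median 1.53). The overlaps therefore do not mean that dnE2f4 ended the rise. Of the 184 targets lower with dnE2f4 at 9 h, 149 had risen from 3 to 6 h in Multicilin caps, against 47.3 for independent sets (odds ratio 12.6, Fisher exact p = 6.11e-56 across targets, which are not replicates). Planned with 16 libraries this overlap was 0, because no target passed at 9 h. Of the 516 lower at 6 h, 421 had risen from 3 to 9 h (172 for independent sets, odds ratio 9.37), and of the 174 higher at 6 h, 131 had fallen (57.0, odds ratio 6.36). Neither this comparison nor the next was planned. The 3 and 6 h falls shared 47 of the 54 targets lower at 3 h, against 1.39 for independent sets, and the 6 and 9 h falls shared 161.

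Peaks of E2f4-GFP lay at the starts of many centriole genes. With Multicilin a peak lay 344 bases from the start of plk4 (scaffold 68717, 247417 to 269714, plus strand), 109 bases from ccdc67 (scaffold 151039, 908944 to 963273, minus), 149 bases from rttn (scaffold 23301, 2048937 to 2135881, minus), and 10, 105 and 127 bases from the regulators ccno, myb and tp73. A shared peak lay 71 bases from cetn2 and 66 bases from bbs12, whose spans overlap. No peak lay within 1 kb of the most abundant target of cep152 (scaffold 9266, 2778434 to 2887692, minus, nearest 65559 bases), stil (26577 bases), foxj1 (scaffold 71264, 620223 to 626121, plus, 2343 bases) or dnai1 (80027 bases). Starts of further targets with these symbols, as foxj1 has, were not looked up one by one. Of the targets lower with dnE2f4 at 6 h, 272 of 516 had a peak within 1 kb of the start (52.7%), against 23.1% of the 19353 not past the threshold (odds ratio 3.71, Fisher exact p = 1.79e-46) and 31.5% at matched level, which was not tested. Targets higher with dnE2f4 had a peak in 37 of 174 cases (21.3%, odds ratio 0.9, Fisher exact p = 0.651), against 28.6% at matched level. With the block the share was 24.9% (odds ratio 1.19, Fisher exact p = 0.00812 against targets not past the threshold), below the 26.6% at matched level.

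The set without Multicilin held 15693 peaks and the set with it 12778, from 24997566 and 15313243 tags. With Multicilin, 5926 peaks (46.4%) overlapped a peak of the other set, against 61 after a 10 kb move, and 37.0% lay within 1 kb of a start (41.5% in the set without). Near lower targets the set without Multicilin also had peaks, in 51.9% of cases against 32.2% (odds ratio 2.27) and 41.4% at matched level, which was not tested. With the block, 42.0% of lower targets had a peak of the set with Multicilin, against 30.2% at matched level. For the set without Multicilin the block gave 42.9% against 40.9% at matched level, so little excess was left there. Targets with a peak in both sets were lower in 6.32% of 3702 cases, with a peak only with Multicilin in 3.54% of 1074, only without it in 1.18% of 2870, and with neither in 1.69% of 12397. Targets with a peak in a single condition differed in that share between conditions (odds ratio 3.06, Fisher exact p = 5.55e-06). That test was not planned. A single pooled sample per condition and different tag numbers leave any difference in binding between conditions untested. Dexamethasone is also given only for the set with Multicilin, so hormone and Multicilin cannot be told apart.

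By list, with Multicilin, a peak lay within 1 kb of the start in 60 of 88 centriole assembly targets (68.2%, against 23.6% of all other targets, Fisher exact adjusted p = 1.29e-17, and 34.6% at matched level, not tested), 78 of 118 G1/S targets (66.1%, Fisher exact adjusted p = 3.73e-21 against all other targets), 26 of 41 multiciliated-cell regulators (63.4%, Fisher exact adjusted p = 3.57e-07) and 68 of 139 G2/M targets (48.9%, Fisher exact adjusted p = 8.76e-10). Axoneme genes had 46 of 118 (39.0%, Fisher exact adjusted p = 0.00106 against all other targets), no more than the 39.7% at matched level. Stress genes had 25 of 58 (43.1%, Fisher exact adjusted p = 0.00495). Against 23.9% of all other targets, peaks were fewer near ionocyte genes (2 of 37, or 5.41%, Fisher exact adjusted p = 0.0151) and mesoderm genes (0 of 18, Fisher exact adjusted p = 0.0252). At matched level the shares were 24.6% and 10.6%, and neither was tested. The other lists did not pass: transport and BBSome genes (23 of 69, 33.3%), Notch genes (13 of 31, 41.9%), housekeeping genes (11 of 29, 37.9%), goblet genes (5 of 47), small secretory cell genes (1 of 13), basal genes (1 of 8), neural genes (9 of 42), neural crest genes (3 of 16), endoderm genes (1 of 23) and dexamethasone genes (2 of 11). The set without Multicilin also had peaks at 63 of 88 centriole assembly targets (71.6%), 93 of 118 G1/S targets (78.8%), 30 of 41 regulators (73.2%), 91 of 139 G2/M targets (65.5%) and 41 of 118 axoneme targets (34.7%). The tests of peaks by list were not among those planned.

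**Figure D4:**
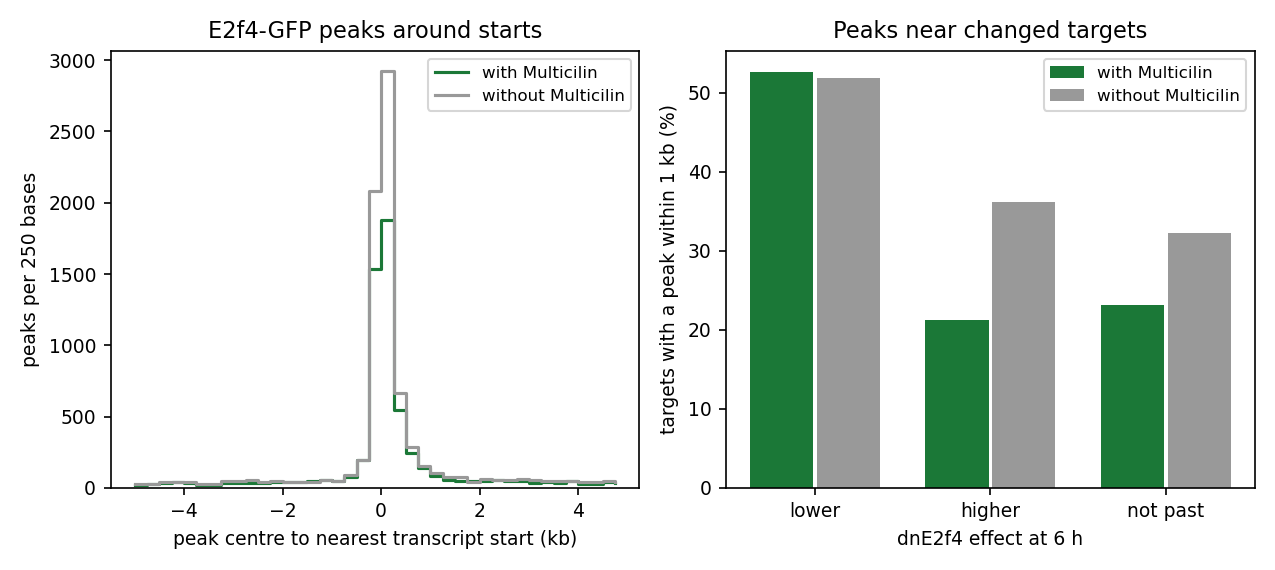
Left, peaks per 250 bases against distance in kb from peak centre to the nearest target start, for both sets; right, percent of targets with a peak within 1 kb by response to dnE2f4 at 6 h. With Multicilin 52.7% of lower targets had such a peak, against 21.3% of higher ones and 23.1% of those not past the threshold.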

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

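Every test in this part was chosen after the results were seen, except that e2f4 was set beforehand as the check on labels.

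The e2f4 level set both libraries labelled replicate 2 at 9 h against their labels. An exchange of labels may account for it, since the centriole assembly genes, which play no part in the e2f4 check, were also higher by a median log2 CPM of 1.24 in the library labelled dnE2f4. Loss of the injected RNA from the library labelled dnE2f4 alone is excluded by the 1520 CPM in the library labelled Multicilin. A mixture of both kinds of cap is excluded by the 15.7 CPM in the library labelled dnE2f4, as low as in Multicilin libraries. The deposited data cannot say whether tubes or file names were exchanged.

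Peaks lay near 52.7% of targets lower with dnE2f4 at 6 h (95% interval 48.4 to 57.0). High expression might favour peaks, but targets of matched level had them in 31.5% of cases, below that interval. With the block the shares were 42.0% and 30.2%. These values argue against level as the whole cause but do not exclude it. Level was the mean over all 6 h libraries, including those in which dnE2f4 lowers these targets, and the interval treats targets as independent. After the peaks with Multicilin were moved 10 kb, 1.55% of lower targets had a peak within 1 kb of the start. Targets higher with dnE2f4 also dropped, from 21.3% to 1.72%, because peaks gathered at starts in both groups. The move therefore shows only that peaks kept to starts. It cannot tell why lower targets had more of them. Whether E2f4 acts at these starts was not tested.

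Less Multicilin RNA in the dnE2f4 caps could lower centriole genes without any part for E2f4. At 6 h, 11 of 88 centriole targets fell further than the most abundant mcidas target by more than 2 standard errors of the difference. With the block 21 did. Those targets speak against a response in proportion to the dose. A response steeper than the dose is not ruled out, so the explanation stays open. The mcidas level mixes injected and native RNA. Summed by symbol, mcidas at 6 h with dnE2f4 was 0.616 of its level without it, and centriole targets were not compared with that sum.

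The fall in rttn deepened by -1.83 from 3 to 6 h and by -2.3 from 3 to 9 h, the single target edgeR called in either test from 14 libraries, and each call was lost on leaving out most single libraries compared. With DESeq2 23 and 115 targets passed, and with the block 48 and 157. Estimated counts on targets outside the common set were 27.9% in replicate 1 of dnE2f4 at 3 h and 25.7% in replicate 3 of dnE2f4 at 9 h, and those fragments entered no test by target.

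Libraries were also split in every other way, and with 10 splits, or 4 that keep the block, the share cannot fall under 0.05. At 6 h the labels gave 690 calls and the highest other split 0 in 14 libraries (1 of 10 splits reached the count), 3191 and 0 with the block (1 of 4), and 0 and 0 in 16 libraries (10 of 10). Over time in Multicilin caps the labels gave 9486 and 12909 calls and the highest other split 0 and 0 (1 of 10 each). At 3 h by symbol they gave 92 and 17 (1 of 10). At 9 h by symbol in 18 libraries the labels gave 0 and another split 2078 (10 of 10). That split exchanges the libraries labelled replicate 2, so it points to structure of the samples.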

How the results depend on the processing

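The 14-library fit and alternatives to it were chosen after the result was seen. The exception is compared groups of 3 and 6 h alone, which hold neither library of the 9 h pair. Chosen after the result as well were the block on compared groups alone and every fit by symbol on 18 libraries. The join of 18 libraries by name was added once the target sets were found to differ. The other alternatives were set before the data were examined. Of the values answering a comparison 275 stayed the same, 94 moved by more than 1.5 times, 3 weakened and 1 reversed. Counts by symbol, taken over fewer features than counts of targets, are among the 94. Counts of 0 that stayed 0, as in most dnE2f4 fits on 16 libraries, are among the 275. The tally therefore does not measure how stable the dnE2f4 calls were. Alternatives that rank peaks by score were not run, because the scores are all the same value. Depth ran from 9159519 to 38099850 fragments with 1 to 3 libraries per group. In the self-test without a block most planted changes of 2-fold or less were not called, and whether depth or library number limits this was not tested. The cause of each movement was not tested.

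For dnE2f4 at 3 h the 16 libraries called 0. DESeq2 called 37, the compared groups alone 2 (1263 with a block), the block 1, 18 libraries joined by name 1, by symbol 1, by symbol with the target set as a term 1, by symbol without the 9 h pair 92, and the 14 libraries 57 (621 with a block). At 6 h, against 0, the values were DESeq2 137, compared groups alone 403 (4294 with a block), 14 libraries 690 (3191 with a block) and by symbol without the pair 509. At 9 h, against 0, they were DESeq2 1, 14 libraries 227 (2175 with a block) and by symbol without the pair 609. The change from 3 to 6 h, against 0, gave 2 from compared groups alone (54 with a block), 1 from 14 libraries (48 with a block) and 2 by symbol without the pair. The change from 3 to 9 h, against 0, gave DESeq2 1, 14 libraries 1 (157 with a block) and 15 by symbol without the pair.

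Against 9486 for 6 over 3 h in Multicilin caps, 6249 changed at least 2-fold and 6216 passed by symbol in 18 libraries. Against 12909 for 9 over 3 h there were 8360 by symbol, 8159 in 18 libraries, 8287 with the target set as a term and 8316 without the pair. Against 11881 for dnE2f4 caps 7761 passed by symbol. Fits by symbol tested 12210 symbols in 16 libraries, 12135 in 18 and 12291 without the pair, against 19567 targets. Lower counts by symbol therefore do not mean that a smaller share passed. The same limit applies to the other counts by symbol in this part.

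From the 14 libraries, 57 at 3 h became 90 with a mean of at least 5 CPM, 403 with DESeq2, 2 with compared groups alone, 621 with the block, and 92 by symbol with the other target set (418 with the block). The 690 at 6 h became 340 at 2-fold, 1409 with DESeq2, 403 with compared groups alone, 3191 with the block and 1731 by symbol with the other set and the block. The 227 at 9 h became 1058 with DESeq2, 1 with compared groups alone, 2175 with the block, and 609 by symbol with the other set (2317 with the block). The change from 3 to 6 h, 1, became 23 with DESeq2, 2 with compared groups alone, 48 with the block, and 2 by symbol with the other set (50 with the block). The change from 3 to 9 h, 1, became 0 with library size alone, 115 with DESeq2, 0 with compared groups alone, 157 with the block, 2 by symbol, 15 by symbol with the other set and 491 with the block added.

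The block on 14 libraries took replicate numbers to mean the same at every time, which was not checked. It raised every dnE2f4 count from 14 libraries by more than 1.5 times, so calls without it are the fewer. It turned the 9 h medians of neural crest genes to 0.13 (fry adjusted p = 0.0303) and housekeeping genes to 0.1 (fry adjusted p = 0.0406), and the share of peaks near higher targets to 24.9%. Centriole medians in 16 libraries were -0.67, -0.87 and -0.18 (fry adjusted p = 0.345, 0.181 and 0.922), so leaving out the pair moved the size of the fall at 9 h alone, and at 3 and 6 h it moved the adjusted p and not the median. The second e2f4 target at 3 h fell by -0.44 with uniquely assigned counts. The overlap with the time course was 149 from 14 libraries against 0 from 16, and 421 for the other pair of comparisons (1418 with the block). Moved peaks overlapped 61 times.

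Single libraries mattered. At 3 h the 57 became 16, 3 and 202 without Multicilin replicate 1, 2 and 3, and 2 and 2 without dnE2f4 replicate 2 and 3. They also became 21 without replicate 2 of Multicilin at 6 h and 32 without replicate 2 of dnE2f4 at 6 h. At 6 h the 690 became 431 and 205 without Multicilin replicate 2 and 3, 241 and 285 without dnE2f4 replicate 2 and 3, and at most 721. At 9 h the 227 became 27 without Multicilin replicate 3 and 271 without Multicilin replicate 1. The change from 3 to 6 h for rttn held (1) without replicate 1 of Multicilin at 3 h or 6 h or replicate 3 of dnE2f4 at 3 h, and was lost (0) without any other library compared. Its change from 3 to 9 h was lost (0) without Multicilin 3 h replicate 2 or 3, dnE2f4 3 h replicate 2 or either Multicilin library at 9 h. In 16 libraries dnE2f4 counts reached 1 at 3 h without Multicilin replicate 3, 0 at 6 h, and 3 at 9 h without dnE2f4 replicate 1. For 6 over 3 h the dnE2f4 caps went from 8212 to 5438 without dnE2f4 3 h replicate 2 and to at most 7374, and Multicilin caps ranged from 7946 to 8472. Ranges for 9 over 3 h were 11782 to 12980 and 9838 to 10371. Centriole medians ranged from -0.73 to -0.61, -0.92 to -0.8 and -1.33 to -1.13.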

Other observations

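The comparisons below were added after the results were seen, beyond those set before the data were examined.

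Peaks in both sets went with the largest share of lower targets, 6.32% of 3702, against 3.54% of 1074 for peaks seen only with Multicilin. In the set without Multicilin 51.9% of lower targets had a peak, against 41.4% at matched level, and after a 10 kb move 1.94% did. With the block the share in that set was 42.9%, close to the 40.9% at matched level. A sample per replicate would be needed to test a gain of binding.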
